A study of Mus musculus with 24 samples.

How the data were processed

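Liver and lung RNA of female BALB/c mice was measured on 24 Illumina bead arrays, 12 per tissue, in 4 groups of 3 arrays per tissue defined by injection (sham or 4T1 cells) and diet (control or high-fat). Per the labels, mice were 22 weeks old, RNA was isolated with Trizol and cleaned on RNeasy columns, and biotin-labelled cRNA was made from 0.55 µg of RNA with the TotalPrep kit of Illumina. Groups and replicate numbers were taken from the sample titles, and each data column was tied to a sample by its sample label.

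The deposited probe intensity values are mean bead signals without normalization, as their header and values show, and ranged from 94.5873 to 71184.1. They were exported with GenomeStudio 2009.2, per the submitters' processing notes. The deposited detection p-value of each probe and array, per the file headers, gives the rank of its signal among negative-control probes, and its steps correspond to 936 such probes. A second deposited table holds log2 values. Against quantile-normalized log2 signals without background correction, computed within each tissue, 99.9997% of its probe-array pairs lay within 0.01 and 3 pairs lay further away. Other scanner settings and upstream steps are not given in the sources used here. Because quantile normalization gives every array of a tissue the same distribution of signals, a change is always relative to the rest of the transcripts on the array.

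Signals were processed per tissue with neqc of limma 3.58.1 in R 4.3.3 (with jsonlite 2.0.0 and version 1.17.8 of data.table), which corrects background by a normal-exponential model with the mean and SD of negative controls inferred from the detection p-values, adds an offset of 16, quantile-normalizes and takes log2. A probe was kept when its detection p was under 0.05 on at least 3 of the 12 arrays. Of 45281 probes, 34885 have 1 gene symbol in the platform annotation, 18 have several and 10378 have none. Probes without exactly 1 symbol were left out of the tests. Symbols were updated through Entrez identifiers (34807 probes) or accessions (11), and 67 were kept as annotated. In all 10 changed. Each gene was represented by its probe with the highest mean over the arrays of the tissue, chosen without regard to group, which left 10904 genes in liver, 12746 in lung and 10365 in a fit of all 24 arrays normalized together. Among genes named in the text that have another kept probe, at least 1 such probe changed by less than 1/3 as much or in the opposite direction for Chka in liver, Slc39a5 in 4T1 liver, Atf4 in the liver injection comparison on the control diet, Csf3r in sham lung, Tnc in 4T1 lung and Celf4 in the lung interaction. Some named genes given with a log2 change were above background on 1 array only of a compared group of 3, namely Arntl, Chka, Hsd3b5, Mad2l2 and Sult3a2 for diet in sham liver, Prom2 for diet in 4T1 liver, Arntl, Asns, Plk1, Prg2, Prss34, Prtn3 and S100a9 for injection in liver on the control diet, Cyp17a1 for diet in sham lung and Cyp2d26, Itgam, Mup6, Oas3, Prok2 and Serpina6 for injection in lung on the control diet. Above background on 2 such arrays were Per3 for diet in sham liver, Slc39a5 and Trpm6 for diet in 4T1 liver, Cdc20, Ltf, Ly6c1 and Mmp9 for injection in liver on the control diet, Car9 for diet in 4T1 lung and Calcrl for injection in lung on the control diet.

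Groups were compared with limma's lmFit and eBayes over all 12 arrays of a tissue, so that the 4 groups shared an estimate of the spread, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called at an adjusted p under 0.05. The comparisons were diet within each injection, injection on each diet, the diet effect averaged over injections, the diet by injection interaction, and the difference of the injection effect between lung and liver. Where no probe of a gene was above background on any array of the dimmer group, the change is given as "at least N-fold". This bound sets the brighter group's mean log2 intensity against the dimmer group's mean of, per array, the higher of the gene's own value and the lowest value among probes above background.

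Gene lists (35, with 1038 genes, 957 of them with a probe) were tested with limma's camera with a preset correlation of 0.01 when at least 5 members were measured, adjusted over the lists of a comparison, with camera using an estimated correlation and fry beside it. With an estimated correlation 4 of 133 list calls held, which are those of the neutrophil list for injection in both tissues and on both diets. Counts of list members are given over all genes and adjusted over the list alone. Genes were named by a rule: for each comparison of diet or injection, the 10 highest and 10 lowest log2 changes among called genes whose groups did not overlap (5 and 5 for averaged effects, interactions and the lung and liver difference), the 10 smallest p-values where fewer than 5 genes passed, and up to 4 members per list by size of change, called ones first. Gene models and clone names were skipped. The groups, comparisons, tests, lists, naming rule and other settings to be tried were fixed before the data were examined.

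The steps were tested on simulated data in which 200 genes were changed. Each gene had its real mean over the arrays and its real spread pooled over the groups, drawn independently of other genes. Every group thus had the same spread, unlike the real sham and 4T1 groups. The shares recovered therefore do not show how the chance of a call differs between sham and 4T1 mice. Of genes changed 2-fold, 80% were recovered for diet in sham liver, 78% for diet in 4T1 liver, 88% for diet in sham lung, 62% for the liver interaction and 78% for the lung interaction. The other settings fixed at that time were other background corrections and normalizations, the deposited log2 table, other filters on dim probes, other choices of probe, other estimates of the spread, array weights, a fold threshold, the replicate number as a block, and each array left out in turn. A covariate for secreted liver proteins, the removal of a pair of lung arrays and a block of same-numbered liver and lung arrays were added after the data were seen. No slide or scan date is given in the sources used here, so no batch could be fitted. The number of arrays per group, 3, limits the precision of every value.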

Results

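Messenger RNA of liver and lung was measured on 24 bead arrays from female BALB/c mice in a design of 4 groups per tissue with 3 arrays in each. Mice received a control or a high-fat diet for 16 weeks. They were then given either a sham injection or 4T1 cells, a mouse mammary carcinoma line that spreads from the mammary fat pad, and tissue was taken 14 days later. The series calls the mice resistant to obesity, and its stated comparison is that of the diets within each injection. Each array carried 45281 probes. In liver, 34.0 to 36.1% of the probes were above background on sham arrays and 40.4 to 41.5% on 4T1 arrays. In lung the shares were 51.0 to 52.4% on sham arrays and 42.97 to 44.8% on 4T1 arrays. Sham and 4T1 arrays thus differed without overlap in the share detected in both tissues, and no slide is named that would let array batch and injection be told apart. The diet comparisons lie within the sham or the 4T1 arrays. Replicate arrays in the liver sham groups differed from each other by an SD of 0.37 to 0.42 on the log2 scale, against 0.20 to 0.24 in the liver 4T1 groups. Lung went the other way, with 0.20 to 0.23 in the sham groups and 0.24 to 0.31 in the 4T1 groups. The number of arrays limits the precision, and because the labels do not say that replicates were separate mice, p-values measure the spread between these samples.

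**Figure D1:**
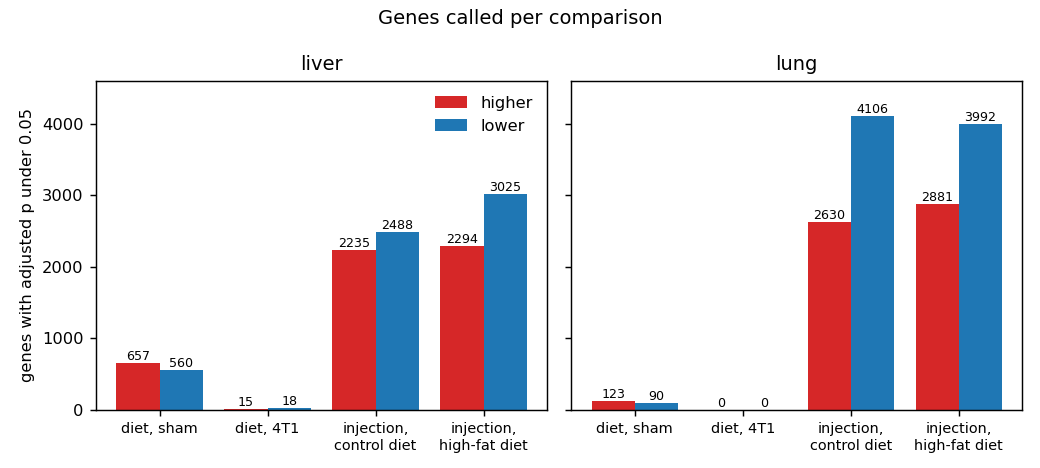
Number of genes called higher (red) or lower (blue) per comparison in liver and lung, with the count above each bar. Both injection comparisons called at least 4723 genes in each tissue, whereas the diet comparison called 1217 genes in sham liver, 33 in 4T1 liver, 213 in sham lung and 0 in 4T1 lung. The groups of a tissue shared an estimate of the spread, although liver sham replicates varied more than liver 4T1 ones and lung sham replicates less than lung 4T1 ones. The counts therefore do not measure how far the diet effect differs between sham and 4T1 mice in either tissue.

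In the liver, genes of neutrophil granules and their precursors were among the most increased after 4T1 injection. On the control diet S100a9, a subunit of the neutrophil protein calprotectin, went from 5.07 ± 0.51 to 13.97 ± 0.07 (log2 intensity, SD, n = 3), a log2 change of 8.91 ± 0.29 (SE), being above background on 1 of the 3 sham arrays. Myeloperoxidase (Mpo) was at least 215-fold higher and the cathelicidin gene Camp at least 67.1-fold higher, since neither was above background on any sham array of this diet. Lactoferrin (Ltf) rose by 7.98, S100a8 by 7.53, the granule protease gene Prtn3 by 6.76 and the eosinophil major basic protein gene Prg2 by 6.45 on the log2 scale. The neutrophil genes Stfa2, Ctsg and Ngp were at least 88.7-fold, 65.3-fold and 61.6-fold higher. On the high-fat diet the increase was 7.65 ± 0.29 for S100a9 and 7.27 for S100a8, while Ltf was at least 351-fold and Mpo at least 271-fold higher. Of the 35 measured genes on the neutrophil and granulocyte precursor list, 34 rose on each diet and none fell, with the same count adjusted over the list alone. The list's median change was 3.82 on the control diet and 4.08 on the high-fat diet (3.50 and 3.47 with undetected genes at their bounds). This list kept its call with an estimated correlation, with camera's adjusted p at 0.00332 and 0.00317.

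Other blood cell genes and acute phase genes also rose in liver. Of 31 genes on the monocyte and macrophage list, 23 rose on the control diet (25 adjusted over the list alone), among them the surface antigen gene Ly6c1 (2.67) and the lysozyme genes Lyz1 (1.83) and Lyz2 (1.68). Values from whole tissue do not tell which cells carried these transcripts. Of 29 positive acute phase genes, 24 rose on the control diet and 25 on the high-fat diet, the same numbers as adjusted over the list alone. They included orosomucoid Orm2 (2.48 and 3.45), serum amyloid Saa1 (2.23 and 2.95) and lipocalin Lcn2 (2.50 and 3.55). Lcn2, Hp, Lrg1 and Pglyrp1 were fixed on both this list and the neutrophil list, so the counts of these lists are not independent. The platelet list had 8 of 11 genes up on the control diet, also 8 adjusted over the list alone, among them the platelet chemokine gene Ppbp (at least 5.98-fold). The mast cell and basophil list had 6 of 7 up, likewise adjusted over the list alone, led by the basophil protease gene Prss34 (3.45). Cell cycle genes rose in 28 of 40 cases and fell in 3 on the control diet (29 and 3 adjusted over the list alone), with the mitotic genes Plk1 at 2.30 and Cdc20 at 2.27. On the control diet these lists had adjusted p = 0.165 (monocytes), 0.204 (acute phase), 0.119 (platelets), 0.146 (mast cells) and 0.146 (cell cycle) with an estimated correlation, so the calls rest on the preset correlation.

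Genes of lipid and drug handling in liver changed in both directions after injection. The squalene epoxidase gene Sqle rose by 2.46 and Msmo1, another sterol synthesis enzyme, by 1.96 on the control diet, where 9 of 18 cholesterol synthesis genes rose and none fell, as many as adjusted over the list alone (adjusted p = 0.449 with an estimated correlation). The complement gene C8a rose by 2.04 and the asparagine synthetase gene Asns by 2.32. The keratin gene Krt23 (-3.47), the acyl-CoA thioesterase gene Acot1 (-2.97), the fatty acid hydroxylase gene Cyp4a14 (-2.76) and the lipoprotein receptor gene Vldlr (-2.39) fell, as did Krt23 (-3.42) and Vldlr (-2.17) on the high-fat diet. Of 25 fatty acid oxidation genes 15 fell and 1 rose on the control diet (16 and 1 adjusted over the list alone), and the median of -0.62 became 0.11 when arrays were scaled by their medians only (adjusted p = 0.212 with an estimated correlation). Of 52 xenobiotic metabolism genes 27 fell, among them Cyp2b10 (-1.40) and Cyp2c29 (-1.08), and 3 rose (28 and 3 adjusted over the list alone), while the median of -0.36 became 0.33 with median scaling (adjusted p = 0.146 with an estimated correlation). Under median scaling Cyp2c29 was not called (limma's adjusted p = 0.144).

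Across all 10904 genes tested in liver, 2235 rose and 2488 fell on the control diet, and 2294 rose and 3025 fell on the high-fat diet. The comparisons share no array, and 1691 genes rose in both (470.2 for independent lists) while 1901 fell in both (690.2). Median scaling moved the median of all genes from -0.03 to 0.66 on the control diet and from -0.06 to 0.73 on the high-fat diet, and the share of increases among the calls went from 47.3 to 97.3% and from 43.1 to 98.2%, so increases and decreases here are relative to an equal distribution of signals. Liver background was 186 on sham arrays and 147 on 4T1 arrays in mean intensity units, a difference that goes with every injection result.

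**Figure D2:**
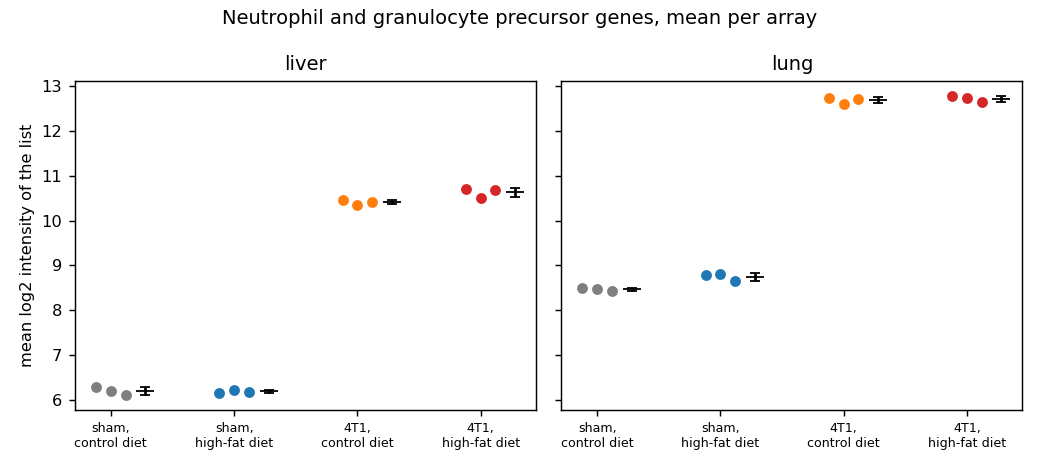
Mean log2 intensity of the neutrophil and granulocyte precursor genes on each array (dots, 3 per group) in liver and lung, with the group mean and SD in black. In both tissues each 4T1 array lay above each sham array.

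In the lung, too, neutrophil genes were among the most increased after 4T1 injection. On the control diet the stefin gene Stfa2 rose from 6.40 ± 0.11 to 15.62 ± 0.14 (SD, n = 3), a log2 change of 9.22 ± 0.14 (SE), and the neutrophil granule gene Ngp rose by 8.93. Prok2, a secreted peptide gene expressed by neutrophils, rose by 8.43, Stfa1 by 8.33, Camp by 8.02 and Ifitm6 by 7.13. Mpo was at least 149-fold and Cstdc5, a stefin relative, at least 71.6-fold higher. On the high-fat diet the changes were 8.76 for Stfa2, 8.51 for Ngp and at least 271-fold for Prok2. Of 37 neutrophil and granulocyte precursor genes 36 rose on each diet and none fell, also adjusted over the list alone, and the call held with an estimated correlation (adjusted p = 0.0161 and 0.0231 with an estimated correlation). S100a8 changed by 4.17 to 16.04 ± 0.00 on the 4T1 control-diet arrays, where the brightest gene of the lung, the haemoglobin gene Hba-a1, stood at 16.08 ± 0.01, so S100a8 and Stfa2, which stood at 15.62 ± 0.14 and 15.63 ± 0.16 on the 4T1 arrays of the control and high-fat diet, were read near the top of the scale and their changes are not measured exactly.

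Some cytokine, interferon response and cell cycle genes of the lung also rose. The interleukin 1 gene Il1b rose by 3.95 ± 0.11 (SE) and oncostatin M (Osm) by 3.38 ± 0.10 on the control diet. Of 30 cytokine and chemokine genes 7 rose and 10 fell there (7 and 11 adjusted over the list alone), and the list, with a median of -0.12, was not called (camera's adjusted p = 0.501, and adjusted p = 0.813 with an estimated correlation). Among 32 genes on the monocyte and macrophage list 15 rose, such as the integrin gene Itgam (2.88) and the chemokine receptor gene Ccr2 (2.33), and 5 fell (16 and 5 adjusted over the list alone), with a median of 0.18 that became -0.18 under median scaling (adjusted p = 0.274 with an estimated correlation). As in liver, the values do not tell which cells carried these transcripts. Of 37 interferon response genes 12 rose, led by the antiviral synthetase genes Oas3 (2.72) and Oas2 (1.99), and 4 fell (12 and 3 adjusted over the list alone), with a median of 0.10 that became -0.36 under median scaling (adjusted p = 0.769 with an estimated correlation). Of 43 cell cycle genes 29 rose and 2 fell on the control diet, and 36 rose and 2 fell on the high-fat diet, equal to the counts adjusted over the list alone. The medians of 0.83 and 1.24 became 0.42 and 0.83 under median scaling, with Birc5 at 1.61 and 2.29 (adjusted p = 0.658 and 0.483 with an estimated correlation). The basophil gene Prss34 rose by 5.73. In this comparison the interferon response list lost its call without sham control-diet array 3 (camera's adjusted p = 0.0719).

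Some alveolar, airway and endothelial genes were lower on 4T1 lung arrays. The alveolar transcription factor gene Nkx2-1 (-1.06) and the phosphate transporter gene Slc34a2 (-0.93) fell on the control diet, where 17 of 23 alveolar genes fell and none rose (19 adjusted over the list alone). The list had adjusted p = 0.345 with an estimated correlation. Of 30 endothelial genes 17 fell, with the receptor gene Calcrl at -1.46 and the lymphatic gene Lyve1 at -0.89, and 1 rose (18 and 1 adjusted over the list alone; adjusted p = 0.658 with an estimated correlation). Of 21 airway genes 9 fell on the control diet, such as Scgb3a1 (-1.16), and 1 rose, the cilia gene Foxj1 (1.14), also adjusted over the list alone. The list was not called (camera's adjusted p = 0.109, and adjusted p = 0.751 with an estimated correlation). On the high-fat diet 14 airway genes fell and 1 rose (16 and 1 adjusted over the list alone; adjusted p = 0.483 with an estimated correlation). Of 18 heat shock genes 12 fell on the control diet and 14 on the high-fat diet, the counts adjusted over the list alone being the same, with the chaperone gene Hsp90aa1 at -1.02 and -1.25 (adjusted p = 0.692 and 0.483 with an estimated correlation).

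Some transcripts known from liver were also lower on the 4T1 lung arrays. Cyp4a14 was at least 9.11-fold lower on the control diet, the major urinary protein gene Mup6 fell by 3.04 and Mup2 fell by 2.60. Of 42 xenobiotic metabolism genes 33 fell and 1 rose on the control diet (35 and 1 adjusted over the list alone), with Cyp2c50 at -2.17 and Cyp2d26 at -2.11 (adjusted p = 0.274 with an estimated correlation). Plasma protein genes that liver secretes, such as Serpina6 (-2.19) and Apoa2 (-1.61), fell in 15 of 25 cases and rose in 2 (16 and 2 adjusted over the list alone; adjusted p = 0.813 with an estimated correlation). This list was fixed beforehand as plasma proteins that fall in the acute phase, so a decrease after 4T1 injection does not by itself point to liver RNA. In liver, however, the mean log2 intensity of the list was higher after injection. On the control diet it was 13.21 to 13.38 on sham and 13.57 to 13.64 on 4T1 arrays. On the high-fat diet it was 13.31 to 13.36 and 13.63 to 13.68. This argues against an acute phase fall of the list as a whole in liver. The list is mixed, however, and holds C8a, which rose in liver. Its mean does not show whether single members such as Apoa2 or Serpina6 fell there. A fall of the lung's own expression was not tested. Of 26 positive acute phase genes 9 rose in lung on the control diet, such as Saa3 (2.96) and Lrg1 (2.66), and 3 fell, also adjusted over the list alone. Their median was 0.12 and became -0.25 under median scaling (adjusted p = 0.658 with an estimated correlation). Lrg1 is also on the neutrophil list. The mean log2 intensity of the secreted liver protein genes, those of the list that falls in the acute phase, differed between lung arrays of a single group, with 8.64 on 4T1 control-diet array 2 against 7.74 and 7.69 on arrays 1 and 3, and with 7.26 on 4T1 high-fat array 1 against 7.76 and 8.31 on arrays 2 and 3. With that mean as a covariate, 23 of the 33 xenobiotic genes were still called lower on the control diet. The plasma protein genes make up that mean, so the covariate is no test of them. Apoa2 lost its call on leaving out sham control-diet array 3, or 4T1 control-diet array 1, with limma's adjusted p up to 0.0513 without 4T1 control-diet array 1, and the secreted plasma protein list lost its call on leaving out sham control-diet array 3, or sham high-fat array 2, or 4T1 control-diet arrays 1 or 3, or 4T1 high-fat array 2, with camera's adjusted p up to 0.132 without 4T1 control-diet array 3.

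**Figure D3:**
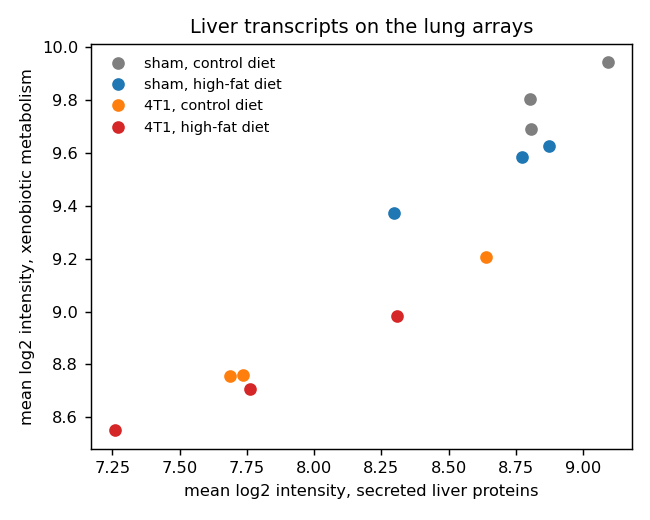
Mean log2 intensity of xenobiotic metabolism genes against that of secreted liver protein genes (fixed as plasma proteins that fall in the acute phase) on the 12 lung arrays, coloured by group. The 4T1 arrays span 7.26 to 8.64 in secreted liver proteins and the sham arrays 8.30 to 9.09.

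Across all 12746 genes tested in lung, 2630 rose and 4106 fell on the control diet, and 2881 rose and 3992 fell on the high-fat diet. Of these, 2241 rose on both diets (594.5 for independent lists) and 3100 fell on both (1286). Median scaling moved the median of all genes from -0.09 to -0.50 on the control diet and from -0.08 to -0.48 on the high-fat diet, and the share of increases among the calls went from 39.04 to 12.0% and from 41.9 to 12.8%. The spread of the lung background, 24.6 intensity units on 4T1 arrays and 14.8 on sham arrays, goes with every injection result.

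The injection effect, averaged over diets, differed between lung and liver for 6274 of 10365 genes, with 3078 higher and 3196 lower in lung. Nlrp12, an immune regulator gene of the NLR family, changed by 0.05 in liver and 4.62 in lung, a difference of 4.56 ± 0.19 (SE). Its probe was already bright in sham liver, with means of 11.11 on the control and 11.70 on the high-fat diet. These lay above its 4T1 lung means of 10.37 and 10.32, so a smaller rise in liver could go unseen. Mrgpra2b rose by 2.35 in liver and 6.08 in lung, the small secreted protein gene Wfdc17 by 1.80 and 5.38, and the gasdermin gene Gsdme by 0.86 and 4.43. Prok2 was also called, and was above background on no sham array in liver and on 1 of 6 in lung, with control-diet 4T1 means of 9.40 in liver and 13.22 in lung. In the other direction the chitinase-like genes Chil3 and Chil4 and the chemokine gene Ppbp changed by -0.14, -0.22 and -0.31 in lung. Their sham lung means on the control diet were already 12.62, 12.61 and 9.24, so a smaller rise in lung could go unseen. In liver these genes were above background on 1, 0 and 0 of 6 sham arrays and on all 6 4T1 arrays, with means of 9.58, 9.37 and 8.99 on the control-diet 4T1 arrays, so the size of their change there is not measured exactly. These liver means lay below the sham lung means. Ltf and S100a9 had larger fitted increases in liver (8.01 and 7.72) than in lung (2.83 and 3.64). In lung their sham control-diet levels were already 13.44 ± 0.18 and 11.56 ± 0.14, and on 4T1 control-diet arrays they stood at 16.03 and 15.53, so that like S100a8 they were read near the top of the scale. Across genes the liver and lung effects correlated with r = 0.458, with genes not being independent replicates. Median scaling moved the median difference of all genes from -0.02 to -1.19 and the share of genes higher in lung among the calls from 49.1 to 2.72%.

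In sham-injected mice circadian clock genes differed between the diets in liver, and the sources used here give no hour of tissue collection. The clock activator gene Arntl went from 5.50 ± 0.67 on the control diet to 8.40 ± 0.08 on the high-fat diet (SD, n = 3), a log2 change of 2.90 ± 0.28 (SE), being above background on 1 of the 3 control-diet arrays. Genes that clock activators drive moved the other way, with the repressor gene Ciart at -3.25 ± 0.31, the deubiquitinase gene Usp2 at -3.29 ± 0.24 and Per3 at -2.38 ± 0.21. Of 15 clock genes 4 rose and 10 fell, as many as adjusted over the list alone. The list was called lower with the preset correlation (adjusted p = 0.354 with an estimated correlation). Other large increases were those of the antisense transcript Hectd2os (3.80 ± 0.20), the choline kinase gene Chka (3.00), the cell cycle inhibitor gene Cdkn1a (2.63), Dnaic1 (2.53), the matrix protein gene Spon2 (2.28), the oxidase gene Nox4 (2.12), Clpx (1.90) and Mad2l2 (1.90).

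Some lipid and steroid genes were lower on the high-fat diet in sham liver. As for the clock genes, collection time and diet cannot be told apart for them. The lipid droplet gene Pnpla3 was at least 8.59-fold lower, and the steroid enzyme genes Hsd3b5 (-3.31) and Cyp17a1 (-2.37) fell. The lipogenic genes Scd1 (-2.05), Thrsp (-2.18) and Elovl6 (-1.71) fell, and of 18 fatty acid synthesis genes 6 fell and 1 rose (6 and 2 adjusted over the list alone; adjusted p = 0.818 with an estimated correlation). Of 25 fatty acid oxidation genes 5 fell and none rose (7 adjusted over the list alone), including Acot1 (-1.66) and Acot3 (-1.60), with adjusted p = 0.354 with an estimated correlation. Of 18 cholesterol synthesis genes 3 rose and none fell, also adjusted over the list alone, and the list was not called (camera's adjusted p = 0.198, and adjusted p = 0.827 with an estimated correlation). In the growth hormone list 3 of 12 genes fell (4 fell and 1 rose adjusted over the list alone), among them Mup5 (-1.16) and the cytokine signalling inhibitor gene Cish (-1.05), with adjusted p = 0.354 with an estimated correlation. Of 37 interferon response genes 7 fell and none rose, also adjusted over the list alone, with Ifit2 at -0.80 and Usp18 at -0.73 (adjusted p = 0.818 with an estimated correlation). Of bile acid genes, Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 1.18 and the bile salt exporter gene Abcb11 rose by 0.86. The neuregulin gene Nrg4 fell by 2.68 and the sulfotransferase gene Sult3a2 fell by 2.84. In all 657 genes rose and 560 fell of 10904, and with median scaling 20.7% of 802 calls were increases against 54.0%. With only the 6 sham arrays in the fit 324 genes were called, with Cyp7a1, Elovl6, Ifit2, Pnpla3 and Usp18 no longer among them (limma's adjusted p from 0.0554 to 0.152), and array weights left 636. Ifit2 lost its call without sham high-fat array 2 (limma's adjusted p = 0.0712), and the fatty acid synthesis list and the interferon response list lost their calls on leaving out sham control-diet arrays 1 or 3 in at least 1 case each, with camera's adjusted p up to 0.288 for the interferon response list without sham control-diet array 1.

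**Figure D4:**
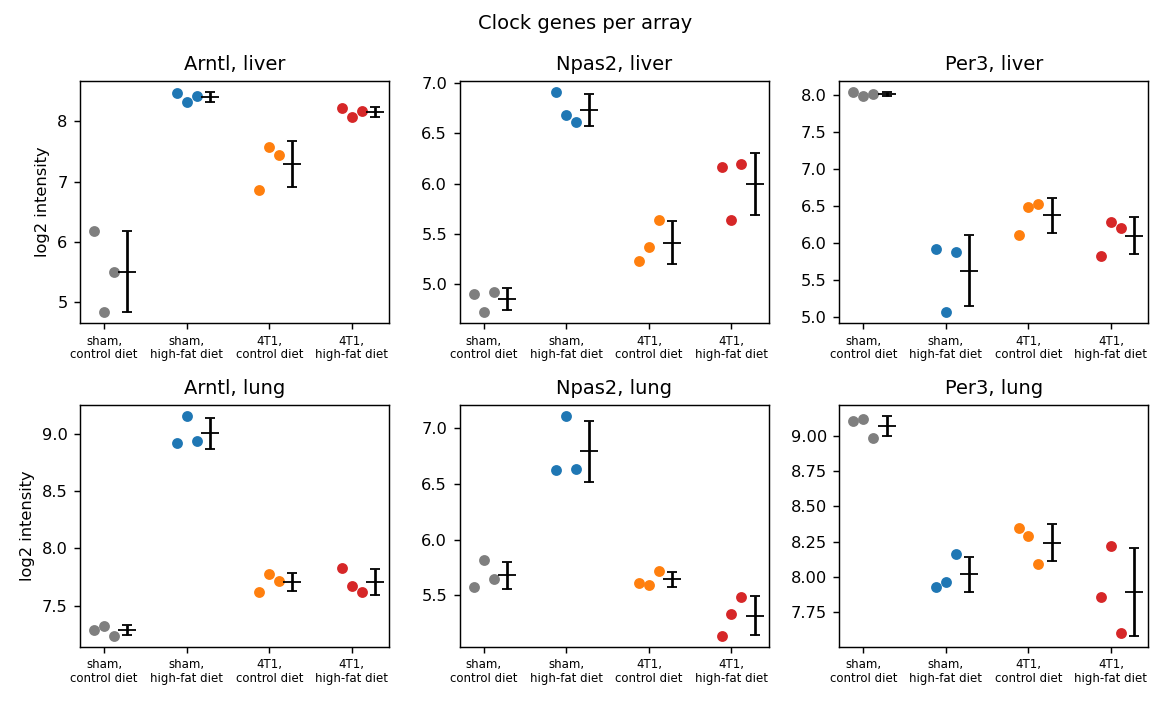
Log2 intensity of the clock genes Arntl, Npas2 and Per3 on each array (dots, 3 per group) with group mean and SD in black, liver above and lung below. In sham mice Arntl and Npas2 lay higher and Per3 lower on the high-fat diet in both tissues.

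In 4T1-injected mice the diet effect in liver was called for 33 genes, 15 higher and 18 lower. Decreases were those of Hsd3b5 (-3.10), Cyp17a1 (-2.45), Scd1 (-1.95), the acetyl-CoA carboxylase gene Acacb (-1.44), the zinc transporter gene Slc39a5 (-1.33), Acot3 (-1.18) and the hepcidin gene Hamp2 (-1.10). The membrane protein gene Prom2 rose by 1.91 ± 0.32 (SE), Cdkn1a by 1.43 ± 0.23, Dnaic1 by 1.40, the glypican gene Gpc1 by 1.31, the magnesium channel gene Trpm6 by 1.22, the deadenylase gene Noct by 1.14 and the nuclear receptor gene Ppard by 0.74. Of the 15 genes that rose, 11 also rose in sham mice, and of the 18 that fell, 16 also fell there (0.904 and 0.924 for independent lists), from arrays that are not shared. No clock gene passed over all genes (3 fell under median scaling), with Arntl at 0.87 ± 0.28 and Ciart at -1.51 ± 0.31, while 6 fell and 2 rose adjusted over the list alone (adjusted p = 0.308 with an estimated correlation). None of 35 neutrophil genes passed alone, also adjusted over the list alone, although the list with a median of 0.25 was called higher with the preset correlation (adjusted p = 0.308 with an estimated correlation). The count was 104 with only the 6 arrays compared and 266 with array weights, while leaving out 1 array gave 61 without sham control-diet array 3, 7, 7 and 5 without 4T1 control-diet array 1, 2 and 3 and 4 and 4 without 4T1 high-fat array 1 and 3. Acacb, Cdkn1a, Dnaic1, Gpc1, Hamp2, Noct, Ppard, Prom2, Slc39a5 and Trpm6 lost their calls on leaving out sham control-diet arrays 1 or 2, or sham high-fat array 2, or 4T1 control-diet arrays 1, 2 or 3, or 4T1 high-fat arrays 1, 2 or 3 in at least 1 case each, with limma's adjusted p up to 0.175 for Trpm6 without 4T1 control-diet array 1.

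Averaged over injections, 437 liver genes were higher and 471 lower on the high-fat diet. Large increases were those of Hectd2os (2.37 ± 0.14), Cdkn1a (2.03 ± 0.17), Chka (1.98), Dnaic1 (1.97) and Arntl (1.89), and large decreases those of Hsd3b5 (-3.20 ± 0.23), Sult3a2 (-2.70), Cyp17a1 (-2.41) and Ciart (-2.38). The interaction of diet and injection was called for 103 liver genes, 18 of which, Map10 among them, had a group without an array above background. Usp2 and Per3 had changed by -3.29 and -2.38 with diet in sham mice and by -1.12 and -0.27 in 4T1 mice, an interaction of 2.17 ± 0.34 and 2.11 ± 0.30 (SE). Median scaling changed the share of increases from 48.1 to 21.8% for the averaged effect and from 51.5 to 75% for the interaction. For Arntl the interaction was -2.03 ± 0.40. With no collection hour given, another collection time for 1 group could also give the interactions of Usp2, Per3 and Arntl. Cish (1.84), Nrg4 (1.72) and the transporter gene Abcc4 (1.65) had positive interactions, and Hectd2os (-2.87), the transcriptional repressor gene Bcl6 (-2.29), Map10 (-1.83) and the matrix signalling gene Ccn4 (-1.79) negative ones. With 1 array left out the interaction count was 50 without sham control-diet array 2, 55 without sham high-fat array 1, 31, 23 and 19 without 4T1 control-diet array 1, 2 and 3 and 20 and 28 without 4T1 high-fat array 2 and 3, and the averaged count was 577 without 4T1 control-diet array 1. Arntl, Ccn4, Nrg4, Per3 and Usp2 lost their calls on leaving out sham control-diet arrays 2 or 3, or sham high-fat arrays 1, 2 or 3, or 4T1 control-diet arrays 1, 2 or 3, or 4T1 high-fat arrays 1, 2 or 3 in at least 1 case each, with limma's adjusted p up to 0.135 for Arntl without 4T1 control-diet array 3.

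In the lung of sham-injected mice Arntl and some neutrophil and B cell genes were higher on the high-fat diet. Arntl went from 7.28 ± 0.04 to 9.01 ± 0.13 (SD, n = 3), a log2 change of 1.72 ± 0.08 (SE), Npas2, its relative, rose by 1.11, and Per2 (-1.26) and Per3 (-1.05) fell. Of 15 clock genes 3 rose and 7 fell (3 and 9 adjusted over the list alone; adjusted p = 0.269 with an estimated correlation). Spon2 rose by 1.83 ± 0.10 and the vasodilator peptide gene Adm by 1.10. Of 37 neutrophil genes 8 rose and none fell (13 rose and 1 fell adjusted over the list alone), with S100a9 at 0.97 ± 0.07, S100a8 at 0.76 and the growth factor receptor gene Csf3r at 0.77 (adjusted p = 0.269 with an estimated correlation). Of 17 B cell genes 7 rose, such as Bank1 (0.87), Fcmr (0.84) and the kinase gene Blk (0.83), and 1 fell (12 and 1 adjusted over the list alone; adjusted p = 0.269 with an estimated correlation). Matrix genes with increases were the collagen gene Col3a1 (0.83) and the lysyl oxidase gene Loxl1 (0.59). Cyp17a1 (-2.00), Acot3 (-1.66), Mup2 (-1.65), the uridine phosphorylase gene Upp2 (-1.33) and Cyp2a5 (-1.25), transcripts that liver also carries, fell. The secreted liver protein mean was 8.80 to 9.09 on the sham control-diet lung arrays and 8.30 to 8.87 on the sham high-fat ones. In all 123 genes rose and 90 fell of 12746. Among the 10414 genes tested in both tissues 99 rose and 77 fell in sham lung, of which 14 and 34 were called in the same direction in sham liver (6.03 and 3.93 for independent lists). The count was 471 with array weights, and leaving out 1 array gave 82, 93 and 51 without sham control-diet array 1, 2 and 3 and 50, 97 and 79 without sham high-fat array 1, 2 and 3. Bank1, Blk, Csf3r, Cyp17a1, Fcmr, Mup2 and Upp2 lost their calls on leaving out sham control-diet arrays 1, 2 or 3, or sham high-fat arrays 1, 2 or 3, or 4T1 control-diet array 1, or 4T1 high-fat array 2 in at least 1 case each, with limma's adjusted p up to 0.160 for Mup2 without sham high-fat array 1.

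In the lung of 4T1-injected mice no gene passed for diet, with limma's smallest adjusted p at 0.1001, although 1436 genes had an unadjusted p under 0.05 where 637.3 would be expected by chance. The genes with the smallest p were Cd207, a Langerhans cell gene, at -0.91 ± 0.12 (SE), Scn3a at 0.43 ± 0.06, the hypoxia-regulated gene Car9 at 0.70 ± 0.11 and Col3a1 at 0.64 ± 0.10. Cell cycle genes had a median of 0.37 and were called higher as a list with the preset correlation, but none of 43 passed alone or adjusted over the list alone (adjusted p = 0.534 with an estimated correlation). The mean of these genes was 9.31 on 4T1 high-fat array 3, against 8.73 and 8.74 on arrays 1 and 2 and 8.65, 8.58 and 8.53 on the control-diet arrays, so that 1 array carries much of the shift. Of 38 extracellular matrix genes none passed over all genes and 9 rose adjusted over the list alone, with the tenascin gene Tnc at 0.78 (adjusted p = 0.534 with an estimated correlation). Arntl stood at 7.70 ± 0.08 on the control diet and 7.71 ± 0.11 on the high-fat diet. The count was 2 without 4T1 high-fat array 2. In simulated data of this comparison, with the same spread in every group, 86% of genes changed 2-fold were recovered. A gene with a wide spread could still be missed, as the largest fitted change, 2.77 in size, was not called.

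Averaged over injections, 46 lung genes rose and 60 fell with the high-fat diet. The protease gene Adamts4 (1.17 ± 0.19), Spon2 (1.13 ± 0.07), Arntl (0.86) and Col3a1 (0.73) had large increases, and Mup3 (-1.46 ± 0.27), the chemokine gene Ccl8 (-0.95) and Acot3 (-0.95) large decreases. Adamts4 was above background on no sham control-diet array and Acot3 on no 4T1 array, so the size of these averages is not measured exactly. The interaction was called for 11 lung genes, with Arntl at -1.72 ± 0.12, Spon2 at -1.39, S100a9 at -1.10 and the adhesion gene Clmp at -1.02. For Arntl another collection time for 1 group could also give this, since no collection hour is given. S100a9 stood at 15.53 and 15.40 on the 4T1 arrays, near the top of the scale. Npas2 and Cyp4a31 were above background on no 4T1 lung array, so their calls do not show a diet effect that differs by injection. The counts were 37 averaged and 5 for the interaction without the 4T1 lung arrays with the highest and the lowest mean of secreted liver proteins (4T1 control-diet array 2 and 4T1 high-fat array 1), a choice made after the data were seen. Without this pair Ccl8 and Mup3 lost their calls in the averaged effect (limma's adjusted p 0.111 and 0.0865) and Clmp, Cyp4a31 and Npas2 in the interaction (0.0626 each). The B cell list was lower in the interaction, with a median of -0.67, no member past the threshold over all genes and 12 of 17 lower adjusted over the list alone (adjusted p = 0.228 with an estimated correlation). With 1 array left out the averaged count was 48, 53 and 33 without sham control-diet array 1, 2 and 3, 38, 59 and 53 without sham high-fat array 1, 2 and 3, 62 without 4T1 control-diet array 1 and 51 and 61 without 4T1 high-fat array 1 and 3, and Adamts4, Ccl8 and Mup3 lost their calls on leaving out sham control-diet arrays 1, 2 or 3, or sham high-fat arrays 1, 2 or 3, or 4T1 control-diet arrays 1 or 2, or 4T1 high-fat arrays 1, 2 or 3 in at least 1 case each, with limma's adjusted p up to 0.1003 for Ccl8 without sham control-diet array 2. The interaction count was 4 without sham control-diet array 3, 6 and 6 without sham high-fat array 1 and 2, 4, 17 and 6 without 4T1 control-diet array 1, 2 and 3 and 3 without 4T1 high-fat array 2, and Clmp lost its call without 4T1 high-fat array 2 (limma's adjusted p = 0.0505).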

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

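Tests of collection time and of the granulocyte lists against random lists were chosen only after the result was seen, and the covariate for secreted liver proteins and the sorting of interaction and averaged splits by the diets they keep were added after the data were seen.

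In liver the interaction test called 103 genes. The interaction was 2.17 for Usp2, 2.11 for Per3, 1.84 for Cish, 1.72 for Nrg4 and 1.65 for Abcc4 on the log2 scale. It was -2.87 for Hectd2os, -2.29 for Bcl6, -2.03 for Arntl, -1.83 for Map10 (above background on no sham control-diet array) and -1.79 for Ccn4. By camera with the preset correlation 6 gene lists were called, against 0 with an estimated correlation (smallest adjusted p = 0.658) and 0 by fry (0.237). The count was 50 without sham control-diet array 2, 55 without sham high-fat array 1, 31, 23 and 19 without 4T1 control-diet array 1, 2 and 3 and 20 and 28 without 4T1 high-fat array 2 and 3. Of 100 splits of the liver arrays 7 called as many genes as the real count of 103, so these splits cannot exclude chance. They do not decide it either. The highest other split, with 908 genes, exchanged the diets within the 4T1 arrays and so is the averaged diet effect, and the other 5 as large kept the real diets of the sham arrays and so carry the diet effect there. The 78 splits that mixed the diets in both injections called at most 2. For the averaged effect no other split reached the real count of 908. This argues against chance as the source of the whole count, although only a random part of the possible splits was run. The highest other, with 324 genes, kept the real diets of the sham arrays only and so carries the diet effect there. The 75 splits of the averaged effect that mixed the diets in both injections called at most 2.

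In lung the interaction test called 11 genes, with 1.26 for Cyp4a31, 1.02 for Celf4 (another probe of which gave -0.06), -1.72 for Arntl, -1.44 for Npas2, -1.39 for Spon2, -1.10 for S100a9 and -1.02 for Clmp. Cyp4a31 and Npas2 were above background on no 4T1 lung array, so their values do not show a diet effect that differs by injection, and S100a9 was near the top of the scale on 4T1 arrays. Celf4, Cyp4a31 and Npas2 lost their calls on leaving out sham control-diet arrays 1, 2 or 3, or sham high-fat arrays 1, 2 or 3, or 4T1 control-diet arrays 1, 2 or 3, or 4T1 high-fat arrays 1, 2 or 3 in at least 1 case each, with limma's adjusted p up to 0.133 for Celf4 without sham control-diet array 3. Without the 4T1 lung arrays highest and lowest in secreted liver proteins Clmp, Cyp4a31 and Npas2 (0.0626 each) and Celf4 (0.0648) lost their calls. By camera 11 lists were called with the preset correlation, against 0 with an estimated correlation (smallest adjusted p = 0.228) and 2 by fry. The count was 4 without sham control-diet array 3, 6 and 6 without sham high-fat array 1 and 2, 4, 17 and 6 without 4T1 control-diet array 1, 2 and 3 and 3 without 4T1 high-fat array 2. Of 100 splits 5 called as many genes as the real count of 11, so these splits cannot exclude chance, and as in liver they do not decide it. The other 4 as large kept the real diets of the sham arrays and so carry the diet effect there, among them the highest, with 93 genes, which moved 4T1 control-diet array 2 and 4T1 high-fat array 1. The 78 splits that mixed the diets in both injections called at most 3. For the averaged lung effect no other split reached the real count of 106. These were a random part of the possible splits, and the highest other came near, so chance is not excluded as the source of the whole count. The highest other, with 93 genes, kept the real diets of the sham arrays only and so carries the diet effect there. The 78 splits of the averaged effect that mixed the diets in both injections called 0. These splits do not show that the 4T1 arrays add to the averaged count.

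The injection effect differed between lung and liver for 6274 genes in the test of the difference, by 4.56 for Nlrp12, 4.07 for Prok2, 3.73 for Mrgpra2b, 3.59 for Wfdc17 and 3.57 for Gsdme, and by -5.18 for Ltf, -5.16 for Chil3, -4.92 for Chil4, -4.08 for S100a9 and -4.03 for Ppbp. Of these, Prok2, Chil4 and Ppbp were above background on no sham liver array, Chil3 on 1 and Ltf on 2 of 6, and Ltf and S100a9 were near the top of the scale in 4T1 lung, so the sizes of these differences are fitted values. Nlrp12 was already bright in sham liver, and Chil3, Chil4 and Ppbp in sham lung, so a smaller rise there could go unseen. Chance as the source of the whole count is argued against by 100 splits, a random part of those possible, the highest other of which called 4697 genes. In the comparisons of 3 with 3 arrays the 10 splits are too few for a share under 0.05. There the real and the highest other counts were 1217 and 26 for diet in sham liver, 33 and 0 for diet in 4T1 liver, 4723 and 5319 against 0 for injection in liver on either diet, 213 and 1 for diet in sham lung, 0 and 7 for diet in 4T1 lung, and 6736 and 6873 against 0 for injection in lung on either diet. All 10 splits reached the count of 0 by limma in 4T1 lung (1436 genes at an unadjusted p under 0.05), and in the other 7 comparisons only 1 split, the real one, reached the count.

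Probes without exactly 1 gene symbol, which entered no comparison, were above background on all 6 4T1 arrays and on no sham array in 107 cases in liver and 86 in lung of 10396. The reverse held for 2 in liver and 237 in lung.

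The shift of clock genes between diets in sham mice was weighed first. Background correction or normalization as its cause is argued against by the 13 of 14 called liver clock genes that were called in the same direction under median scaling, the lowest number among the other background corrections and normalizations. Another time of day at tissue collection for 1 diet group could also give the shift, since all 14 genes had the same sign in lung and 10 were called there. A diet effect on the clock of the whole animal predicts the same, and no collection hour is given in the sources used here, so collection time and diet cannot be told apart for these genes. The same limit holds for the other genes called between the diets in sham mice. It also holds for the clock genes in the injection comparisons and the interactions, where another collection time for 1 group could give the changes.

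Liver transcripts on lung arrays were weighed second. Liver RNA in the lung samples may be their source, since the first component of the secreted liver proteins held 87.0% of their variance within groups, against 56.3% at the 95th percentile of 1000 random lists and at most 86.9% in any. The random lists were matched on mean level only, so other genes that vary together could also pass. The secreted liver protein list was fixed as plasma proteins that fall in the acute phase, so a common response of these genes could also give such a component. Of 27 listed genes 25 were above background in lung, so the lung's own expression of them is not separated, and those with the brightest probes, chosen after their values were seen, were Trf at 13.93 ± 0.16, Serpina1b at 12.95 ± 0.20 and Ttr at 12.77 ± 0.32 (log2 intensity, SD, n = 3) on sham control-diet arrays. Lung 4T1 control-diet array 2, highest of its group in secreted liver proteins, was also highest in adipocyte genes (mean 9.40 against 8.99 and 8.58). The same held for heart and skeletal muscle genes (11.23 against 10.61 and 10.30). In the 4T1 high-fat group array 3, highest in secreted liver proteins, was highest in neither. For the lower xenobiotic genes in 4T1 lung the source cannot be told apart from an injection effect, since 23 of 33 stayed lower with the secreted liver proteins as a covariate, their list's median going from -0.73 to -0.48. An effect of injection on the lung itself, which the design names, stays open.

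The large share of genes called for injection was weighed last, against an array batch or background that goes with the injection. In lung such a batch may contribute, since 22.1% of 17898 probes above background on no array differed by injection and 0 by diet in limma's test (1020 probes at an unadjusted p under 0.05). In liver 1.66% of 21204 did and 0 by diet (1137), which argues against a shift of background left after background correction as the source there. The background of each array was subtracted before this test, so it does not bear on the uncorrected difference in background. These probes cannot show a batch that scales signals, and liver background did not overlap between injections, so batch and injection cannot be told apart for the counts as a whole. The granulocyte list's median change averaged over diets was 3.98 in liver and 4.02 in lung. The highest of 10000 random lists matched on mean level reached 0.33 and 0.19. For the granulocyte genes this argues against a shift, left after normalization, that moves genes of similar level alike. Normalization had already removed a shift common to all transcripts, so the random lists are no test of it. They also cannot show a batch that acts on particular transcripts. A biological effect of the 4T1 cells on these genes is a hypothesis that stays open.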

How the results depend on the processing

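Fits with secreted liver proteins as a covariate, without a pair of lung arrays and with same-numbered liver and lung arrays as a block were chosen only after the result was seen. Counts of called genes stayed within 1.5 times those in the report, except for the values given here, no named gene turned its direction, and no named list did in the settings run for lists (median scaling, which turns some list medians as given with those lists, was not among them). Where a stricter or looser threshold, fewer arrays or another number of genes tested does not account for a move by construction, the cause was not tested. Signal over background limits the dim genes, since those above background on fewer than 3 arrays of a tissue were not tested.

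Diet in sham liver (1217 genes) gave 802 with median scaling, 324 with only the compared groups, 636 with array weights, 539 at 1.5-fold and 719 at an unadjusted p and 1.5-fold. Diet in 4T1 liver (33) gave 170 without background correction and 170 with the deposited log2 table, 88 with normexp and an offset of 50, 57 with median scaling, 51 with a stricter filter, 139 with a trend and robust spread, 104 with only the compared groups, 266 with array weights and 123 at an unadjusted p and 1.5-fold. The liver interaction (103) gave 222 without background correction or with the deposited table, 52 with median scaling, 39 without a filter, 204 with a trend and robust spread and 568 at an unadjusted p and 1.5-fold.

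Diet in sham lung (213) gave 369 without background correction or with the deposited table, 133 without a filter, 442 with a trend and robust spread, 471 with array weights, and 70 and 138 at 1.5-fold with an adjusted and an unadjusted p. Diet in 4T1 lung, with 0 genes by limma and 1436 at an unadjusted p under 0.05, gave 2 without background correction, with the deposited table or with every probe tested, 1 with a trend and robust spread, 125 at an unadjusted p and 1.5-fold, 4 with the covariate and 1 without the pair of arrays. The averaged lung effect (106) gave 218 without background correction or with the deposited table, 61 without a filter, 160 with a stricter one, 254 with a trend and robust spread, 21 and 64 at 1.5-fold and 37 without the pair. The lung interaction (11) gave 36 without background correction or with the deposited table, 24 with normexp and an offset of 50, 18 with all arrays normalized together, 7 and 21 without and with stricter filters, 63 with a trend and robust spread, 271 at an unadjusted p and 1.5-fold and 5 without the pair.

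Injection called 8443 and 8881 genes in liver and 10458 and 10364 in lung (control and high-fat diet) with median scaling, and the lung and liver difference 9709. At 1.5-fold with an adjusted and an unadjusted p the counts were 2162 and 2272 (liver, control diet), 2494 and 2591 (liver, high-fat), 2599 and 2626 (lung, control), 2832 and 2869 (lung, high-fat), 3228 and 3299 (lung against liver) and 218 and 234 (averaged diet effect in liver). Of 133 list calls 4 held with an estimated correlation, and fry called 136.

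With 1 array left out the counts ran from 837 to 1158 for diet in sham liver, 4 to 61 in 4T1 liver, 3748 to 4861 and 4484 to 5527 for injection in liver, 577 to 940 averaged and 19 to 111 for the interaction. In lung they ran from 50 to 225 for diet in sham mice, 0 to 2 in 4T1 mice, 5739 to 6843 and 5968 to 6922 for injection, 33 to 106 averaged and 3 to 17 for the interaction, and elsewhere from 6045 to 6456 for lung against liver and 126 to 143 for list calls. Moves of over 1.5 times were, for liver, 61 without sham control-diet array 3, 7, 7 and 5 without 4T1 control-diet array 1, 2 and 3 and 4 and 4 without 4T1 high-fat array 1 and 3 (4T1 diet), 577 without 4T1 control-diet array 1 (averaged) and 50 without sham control-diet array 2, 55 without sham high-fat array 1, 31, 23 and 19 without 4T1 control-diet array 1, 2 and 3 and 20 and 28 without 4T1 high-fat array 2 and 3 (interaction). For lung they were 82, 93 and 51 without sham control-diet array 1, 2 and 3 and 50, 97 and 79 without sham high-fat array 1, 2 and 3 (sham diet), 2 without 4T1 high-fat array 2 (4T1 diet), 48, 53 and 33 without sham control-diet array 1, 2 and 3, 38, 59 and 53 without sham high-fat array 1, 2 and 3, 62 without 4T1 control-diet array 1 and 51 and 61 without 4T1 high-fat array 1 and 3 (averaged) and 4 without sham control-diet array 3, 6 and 6 without sham high-fat array 1 and 2, 4, 17 and 6 without 4T1 control-diet array 1, 2 and 3 and 3 without 4T1 high-fat array 2 (interaction).

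Of the named genes, leaving out an array ended a call in 168 cases over 31 genes and made one in 1, and other settings ended 71 over 32 and made 19 over 6. The named genes whose calls other settings ended, with limma's adjusted p, were Cyp7a1, Elovl6, Ifit2, Pnpla3 and Usp18 for diet in sham liver (up to 0.152 for Ifit2 with only the compared groups), Acacb, Cdkn1a, Noct, Ppard, Prom2, Slc39a5 and Trpm6 for diet in 4T1 liver (up to 0.342 for Slc39a5 with all arrays normalized together), Atf4 and Cyp2c29 for injection in liver on the control diet (up to 0.144 for Cyp2c29 with median scaling), Arntl, Ccn4, Nrg4 and Per3 for the liver interaction (up to 0.142 for Arntl with all arrays normalized together), Bank1, Blk, Cyp17a1, Mup2 and Upp2 for diet in sham lung (up to 0.0752 for Cyp17a1 with only the compared groups), Apoa2 and Serpina6 for injection in lung on the control diet (up to 0.218 for Serpina6 with the covariate, of which both are part), Adamts4, Ccl8 and Mup3 for diet averaged in lung (up to 0.111 for Ccl8 with the pair of arrays left out) and Celf4, Clmp, Cyp4a31 and Npas2 for the lung interaction (up to 0.190 for Celf4 with the mean of a gene's probes). Of the named lists, leaving out an array ended 8 calls over 4 lists and made 2 while other settings ended 44 over 37 and made 3.

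Same-numbered arrays were fitted without a block, since the labels do not pair them and in no comparison did every same-numbered pair correlate above 0.1 (from -0.18 to 0.29 over all pairs). Within a tissue, no comparison had all 6 samples correlating best with their own number, the number that did running from 0 to 2. Between liver and lung of a group all 6 did in the sham high-fat and the 4T1 control-diet group, 4 in the sham control-diet group and 3 in the 4T1 high-fat group, with correlations of same-numbered arrays from -0.02 to 0.09, a hint from the data that is taken up in the last section. With the replicate number as a block, diet called 9 genes in 4T1 liver, 115 in sham lung, 1 in 4T1 lung and 55 averaged in lung, and the interaction 36 in liver and 4 in lung, while other counts stayed within 1.5 times. With same-numbered liver and lung arrays of a group as a replicate block, the lung and liver difference was called for 6152 genes. A slide block was planned and not run, because no slide is named in the files used here.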

Other observations

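The test of same-numbered arrays was chosen only after the result was seen.

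On the control diet 4T1 injection also went with changed clock genes. With no collection hour given, another collection time for 1 group cannot be told apart from injection for them. In liver Arntl rose by 1.79 ± 0.28 (SE), and Ciart (-1.98), Usp2 (-1.87) and Per3 (-1.63) fell, the directions of the diet effect in sham mice, which shares the sham control-diet arrays. Arntl stood at 5.50 ± 0.67 on those arrays against 8.40 ± 0.08, 7.29 ± 0.38 and 8.16 ± 0.08 (log2 intensity, SD, n = 3) in sham high-fat, 4T1 control-diet and 4T1 high-fat liver. Of 15 clock genes in liver 5 rose and 4 fell, as many as adjusted over the list alone, and the list was not called (camera's adjusted p = 0.554, and adjusted p = 0.719 with an estimated correlation), its median of -0.17 becoming 0.55 under median scaling. In lung 12 of 15 fell and 1 rose, also adjusted over the list alone, with Per1 at -1.19, Nr1d2 at -1.02 and Per2 at -0.94 (adjusted p = 0.441 with an estimated correlation).

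Some stress response and T cell genes also moved with injection. Of 23 genes of the unfolded protein and integrated stress response 13 rose and 2 fell in liver on the control diet (14 and 2 adjusted over the list alone), with Sdf2l1 at 1.04, the glutathione-degrading enzyme gene Chac1 at 1.00 and the transcription factor gene Atf4 at 0.97 (adjusted p = 0.212 with an estimated correlation). In lung on the control diet 9 of 25 T cell and natural killer cell genes fell and 2 rose (8 and 2 adjusted over the list alone), and the list, with a median of -0.09, was not called (camera's adjusted p = 0.642, and adjusted p = 0.850 with an estimated correlation). On the high-fat diet 17 of the 25 fell and 2 rose (18 and 2 adjusted over the list alone). The chemokine gene Ccl5 (-1.22), the T cell adaptor gene Lat (-1.10) and the receptor gene Klrd1 (-0.92) fell, whereas the T cell receptor subunit gene Cd3d rose by 0.87 (list median -0.46, adjusted p = 0.521 with an estimated correlation). The protease gene Mmp9, which neutrophils carry, rose by 3.37 in liver and 5.28 in lung on the control diet.

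Same-numbered liver and lung arrays of a group may come from 1 mouse, a hypothesis tested on the deviations of each array from its group mean over 10414 genes. The mean correlation of same-numbered arrays was 0.0454, with an exact one-sided permutation p of 0.00309 over 1296 assignments of numbers within groups, the highest of the others being 0.0481. For 9 of 12 liver arrays the best match among the lung arrays of the group had their own number. The correlation is small, and a shared order of tissue handling was not tested as its source.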
